A study of Arabidopsis thaliana with 8 samples.

How the data were processed

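Total RNA from mature, fully expanded leaves was labelled with biotin and hybridised to single-colour Affymetrix arrays, per the labels' protocols. Plants were 4 weeks old at inoculation and were sampled 5 days later, and infected plants were kept in a separate growth chamber. The labels describe 2 independent experiments and 2 biological replicates per group. They do not state that a replicate number marks an experiment. The authors deposited 1 table of intensities on a linear scale for the 8 arrays, with values from 7.88 to 19450. RMA and Partek are named in the submitters' processing notes, without versions, and neither the genome build nor the background settings were given in the sources used here. Log2 was taken of every value before testing, as foreseen. No pseudocount was needed, since all values were above 0. No column of per-sample values was left unused.

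Of 22810 probe sets, 64 were array controls and were left out of the tests, which covered 22746. Gene names came from the platform's annotation, updated through gene identifiers to the TAIR10.1 gene table. In it 13513 probe sets had 1 gene, 503 had several and 8730 were not listed and stay unnamed here. The named probe sets represented 13356 genes, of which 13286 were found in the gene table and 1535 had a symbol other than their locus tag. For a gene with several probe sets, the one with the highest mean over the 8 arrays was used. No coordinates are given because no build was named.

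The model was fitted with limma 3.58.1 (R 4.3.3): lmFit on all 8 arrays with 4 group means and no block, contrasts for 6 comparisons, and eBayes moderation (4 residual and 1.61 prior degrees of freedom). Two-sided p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets within a comparison, and a probe set was called at an adjusted p under 0.05. Fold changes are ratios of geometric means, standard errors come from the moderated fit, and groups are given as mean ± SD of log2 intensity.

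Arrays of different groups with the same replicate number deviated together: the correlation of their deviations from the group means lay between 0.40 and 0.79 over the 6 pairs of groups, and the first principal component separated the numbers. The numbers were therefore taken to pair the arrays, on the basis of these data, and the fit with the replicate number as a block is quoted beside a result where it changed a call or moved a count by more than 1.5 times. This was settled before the calls of the fits were compared. Otherwise the standard errors and p-values of the 6 comparisons come from the fit without the block. Variation shared by same-numbered arrays stays in its residual spread (median SD 0.190, against 0.159 with the block). Its standard errors thus tend to overstate the uncertainty of differences between same-numbered arrays.

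Gene lists were tested with camera (preset inter-gene correlation 0.01) on 1 probe set per gene, with lists of at least 4 measured members, and adjusted over the lists of one origin within a comparison. Before the data were examined, 21 lists with 330 entries had been fixed; 36 of the entries had a named probe set, and 2 lists could be tested. A further 24 lists with 435 measured genes were drawn up after the gene names of the probe sets were seen and before any difference between groups was computed, and are called added lists. Camera with an estimated correlation and fry were run beside it.

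Genes were named by a rule fixed before the data were examined: a panel of 9 genes, the 6 highest and 6 lowest fold changes among called genes, up to 4 called members of each list, up to 2 members with the smallest unadjusted p where none was called, and, where fewer than 5 genes passed in a direction, the 5 with the smallest unadjusted p. Genes that did not pass are given as values only, and the text names a selection of those the rule gives, chosen after their values were seen.

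The fit was tested on simulated data with the real means, replicate differences and residual spread, in which 200 of 22746 probe sets were changed. For uninfected del1-1 against Col-0 it recovered 24% of 2-fold, 78% of 4-fold, 78% of 8-fold and 82% of 16-fold changes and called 2 unchanged probe sets. For infection in Col-0 it recovered 26%, 64%, 82% and 82%, for infection in del1-1 24%, 56%, 78% and 84%, and for infected del1-1 against Col-0 18%, 68%, 80% and 88%. The fit with the replicate block recovered more, 32%, 80%, 84% and 90% for uninfected del1-1 against Col-0. It also called more unchanged probe sets there, 7 against 2. In the other comparisons, in the order given, it called 8, 9 and 12 unchanged probe sets, against 1, 0 and 1 without the block. The simulation holds no spread peculiar to a single group, and none shared by only some groups of a replicate number, such as those of 1 growth chamber. The adjustment also grows less strict as more probe sets change. These shares may therefore exceed what the real comparisons, those of infection above all, can recover.

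Alternatives fixed before the data were examined were median centring, a further quantile normalization, a filter at the 40th percentile of mean signal, fits of only the groups compared, a fixed or random replicate block, a variance trend, an unmoderated model, 1 probe set per gene, array weights, stricter thresholds and leaving out each array. Fits and list tests without 1 array had no replicate block. A group left with 1 array then no longer balances the replicate numbers, and its comparisons take up part of the difference between the numbers. Ranges and counts without 1 array therefore mix this difference with the effect of the array itself. Figures were drawn with matplotlib 3.10.9.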

Results

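Transcript levels were measured in mature leaves of Arabidopsis thaliana on 8 single-colour oligonucleotide arrays. The plants were the wild-type accession Col-0 and the mutant del1-1, which carries a lesion in DEL1, the gene of an atypical E2F protein that represses transcription and limits endoreduplication. Leaves came from uninfected plants and from plants 5 days after inoculation with Golovinomyces orontii, a powdery mildew fungus that grows on living epidermal cells. Each of the 4 combinations of genotype and infection had 2 arrays. Median intensity per array lay between 37.8 and 39.9, and the number of arrays limits the precision. DEL1 itself, and the panel genes ICS1, EDS5, PR1, PR2, PR5, CCS52A1, CCS52A2 and PHR1, had no probe set with a gene name in the table used, so they were not analysed by name here. Their probe sets may be among those tested without a gene name. The genotype of the arrays therefore rests on their labels.

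The arrays differed more between replicate numbers than between groups. The first principal component held 49.6% of the variance and placed the 4 arrays of replicate 1 on one side and the 4 of replicate 2 on the other. Arrays of different groups with the same number correlated at a median of 0.978 across probe sets, against 0.958 for the pairs of arrays within a group.

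**Figure D1:**
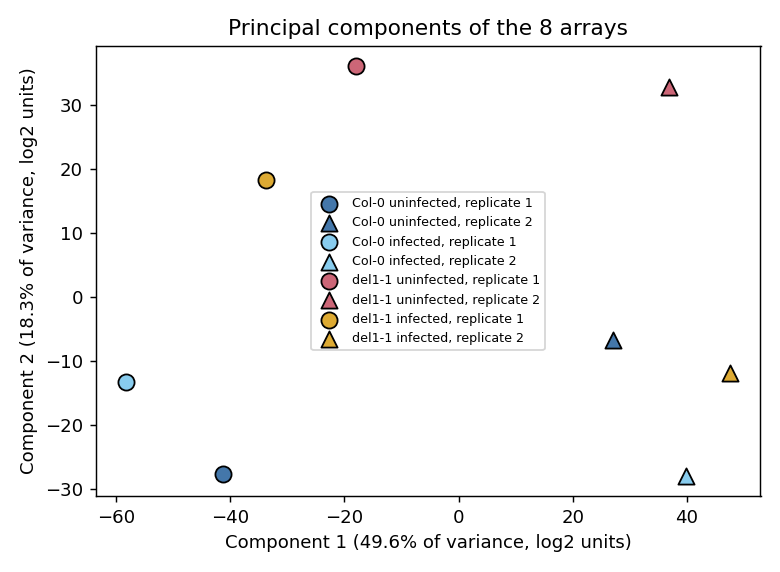
Each point is 1 array, placed by its scores on the first and second principal component of all non-control probe sets (log2 units); colour gives the group and shape the replicate number. Component 1, with 49.6% of the variance, separates replicate 1 from replicate 2, and the uninfected del1-1 arrays have the highest scores on component 2 (18.3%).

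The comparison of uninfected del1-1 with uninfected Col-0 asked what the mutation does to leaf transcripts without the pathogen. AT2G44240 was 30.6-fold higher in del1-1, with log2 intensities of 8.91 ± 0.32 (SD, n = 2) against 3.97 ± 0.21 (SD, n = 2) in Col-0. A probe set without a gene name here was 17.8-fold higher, and a second unnamed one was 8.98-fold higher. These 3 were the probe sets that passed in limma's moderated test, with adjusted p of 0.0136, 0.00718 and 0.036, and each was higher in both uninfected del1-1 arrays than in either uninfected Col-0 array. No probe set was called lower. The uninfected Col-0 values of AT2G44240 (4.12 and 3.83) and of the second unnamed probe set (3.88 and 3.85) were dim. They lay below the median log2 signal of those arrays, 5.24 and 5.31. Signal over background was not analysed, so the size of these 2 folds is uncertain. An unadjusted p under 0.05 was found for 1131 probe sets (2202 with the replicate block), where 1137 would be expected by chance. Without the block, variation shared by same-numbered arrays stays in the residual spread (median SD 0.190, against 0.159 with it). P-values without the block then lean high, here and in the comparisons below. The closeness of 1131 to 1137 is therefore no sign that the genotypes do not differ. For infection in Col-0, infection in del1-1, the infected genotypes and the interaction, the counts with the block (440, 848, 813 and 560) also lay under 1137. The missing block thus does not account for the whole shortage there. Between the uninfected genotypes, with the replicate number as a block, 4 passed, all higher, the 3 above among them. The fourth was AT1G68620, at 6.66-fold (adjusted p = 0.022 with the block and 0.907 without), a gene outside the naming rule that was named after its value was seen.

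Defence-related genes had some of the larger values among those that did not pass. The chitinase gene CHI (AT2G43570) was at 11.56 ± 0.41 (SD, n = 2) in uninfected del1-1 and 7.41 ± 0.04 (SD, n = 2) in Col-0, a 17.8-fold difference (adjusted p = 0.14). CML41, which encodes a calmodulin-like protein, was 5.91-fold higher (adjusted p = 0.153). The subtilase gene SBT3.3 had a log2 difference of 2.14 ± 0.34 (SE), the glucosyltransferase gene UGT76B1 1.95 ± 0.52, the glutaredoxin gene GRX480 1.79 ± 0.46, and the transcription factor genes WRKY6 and WRKY53 1.51 ± 0.19 and 1.31 ± 0.44. BIK1, an immune receptor-associated kinase gene, was 0.61 ± 0.22 higher. Without 1 array UGT76B1 ranged from 1.12 to 2.78, GRX480 from 1.17 to 2.41 and WRKY53 from 0.81 to 1.81. Of 20 named defence genes, 18 were higher in del1-1, with a median log2 difference of 0.60, and the list rose relative to the other genes (camera with a preset correlation, adjusted p = 1.07e-05). That call was lost with an estimated correlation (adjusted p = 0.148 with an estimated correlation).

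Genes of the endoplasmic reticulum moved the same way. ATERDJ3B, a co-chaperone gene of the reticulum lumen, was 2.76-fold higher in uninfected del1-1 (adjusted p = 0.153), the calreticulin gene CRT1b was 3.03-fold higher, and BZIP60, a transcription factor gene of the unfolded protein response, was 2.00-fold higher, none of them past the threshold. Without 1 array the log2 difference of BZIP60 ranged from 0.64 to 1.36. The list of 14 genes of reticulum stress and folding rose, with 13 members higher, a median of 0.43 and adjusted p = 8.78e-09, or adjusted p = 0.089 with an estimated correlation. Beta-glucosidase and ER body genes rose as a list (16 of 27 higher, median 0.18, adjusted p = 0.00402, and adjusted p = 0.275 with an estimated correlation). In that list PYK10, the main glucosidase of ER bodies, had a log2 difference of 1.66 ± 0.25 (SE) and the lectin gene JAL33 0.98 ± 0.16. The 7 calmodulin-like genes also passed (median 0.36, adjusted p = 0.0209), with 4 of 7 higher, an adjusted p = 0.275 with an estimated correlation and an adjusted p = 0.11 with the replicate block.

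Photosynthesis transcripts were lower in uninfected del1-1. Of 43 plastid-encoded photosynthesis genes, 41 were lower, with a median log2 difference of -0.34 (adjusted p = 3.09e-19, and 0.089 as the adjusted p with an estimated correlation). petG, for a subunit of the cytochrome b6f complex, had a difference of -0.98 ± 0.13 (SE), and ndhJ, for a subunit of the plastid NADH dehydrogenase-like complex, -0.71 ± 0.11. All 20 plastid-encoded gene expression genes were lower (median -0.45, adjusted p = 5.38e-11, and adjusted p = 0.275 with an estimated correlation), with rps2 at -1.21 ± 0.39 and rpoC1 at -0.72 ± 0.21. All 24 nuclear genes of photosynthesis and chlorophyll synthesis were lower too (median -0.24, adjusted p = 3.14e-08, and adjusted p = 0.275 with an estimated correlation). PORB, which makes chlorophyllide in the light, was at -0.62 ± 0.11 and NdhN at -0.67 ± 0.18. The 7 measured members of the photosynthesis list fixed before the data were examined were all lower (median -0.18, adjusted p = 0.00346, and adjusted p = 0.228 with an estimated correlation), PSAN of photosystem I among them at -0.47 ± 0.23. The call of this list was lost without Col-0 uninfected replicate 1. Without 1 array PSAN ranged from -0.68 to -0.27 and NdhN from -0.90 to -0.43. Plastid-encoded gene expression genes, nuclear photosynthesis genes and the fixed photosynthesis list also differed between the replicate numbers, with medians of -0.23, -0.18 and -0.19 in replicate 2 relative to replicate 1, calls that were lost with an estimated correlation (adjusted p = 0.706, 0.561 and 0.0872).

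No cell cycle list was called in uninfected del1-1. Of 21 genes of DNA replication, repair and chromatin assembly 10 were higher (median -0.02, adjusted p = 0.92), and of 19 genes of mitosis and the endocycle 9 were higher (median -0.01, adjusted p = 0.865). FBL17, an F-box gene whose product targets inhibitors of cyclin-dependent kinases, was at 0.47 ± 0.11 (SE) on the log2 scale. Mitochondrial respiration genes had a median of 0.12 (adjusted p = 0.0742, and 0.0235 with the replicate block, lost there with an estimated correlation at an adjusted p = 0.298), with SDH1-1 at 0.80 ± 0.24 and NDB2 at 1.23 ± 0.37. The sugar transporter gene TMT2 was at -0.84 ± 0.18, the auxin response gene IAA29 at -2.14 ± 0.50, the kinesin-like gene KICP-02 at -1.77 ± 0.26 and AT4G32460 at -1.23 ± 0.19. All 4 markers of the stomatal lineage were lower, with a median of -0.13 that did not pass (adjusted p = 0.0742). CHX20 in that list was at -0.55 ± 0.28, and from -0.92 to -0.19 without 1 array, where IAA29 ranged from -2.88 to -1.40.

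The count of 3 rests on all arrays sharing 1 estimate of the spread: it was 0 in a fit of these 2 groups alone and 0 without any of the 8 arrays. At least 2-fold differences in the same direction in both same-numbered pairs were found for 275 probe sets higher and 83 lower in del1-1, against 26 that went in opposite directions, a count chosen after the data were seen and without a test. Of the 36 memberships in lists fixed before the data were examined, 0 passed over all probe sets and 4 passed, all higher, when adjusted over the list alone. With the replicate block 7 passed, 1 of them lower, in the list of abscisic acid, cold and water stress. In the added lists 9 members passed higher and 7 lower adjusted over the list alone (31 in either direction with the block). The 4 are in lists with only 1 or 2 measured members, where that adjustment corrects for little or nothing. The fixed list of sugar transport and carbohydrate use, with 3 of 4 genes higher and a median of 0.58, did not pass (adjusted p = 0.085).

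**Figure D2:**
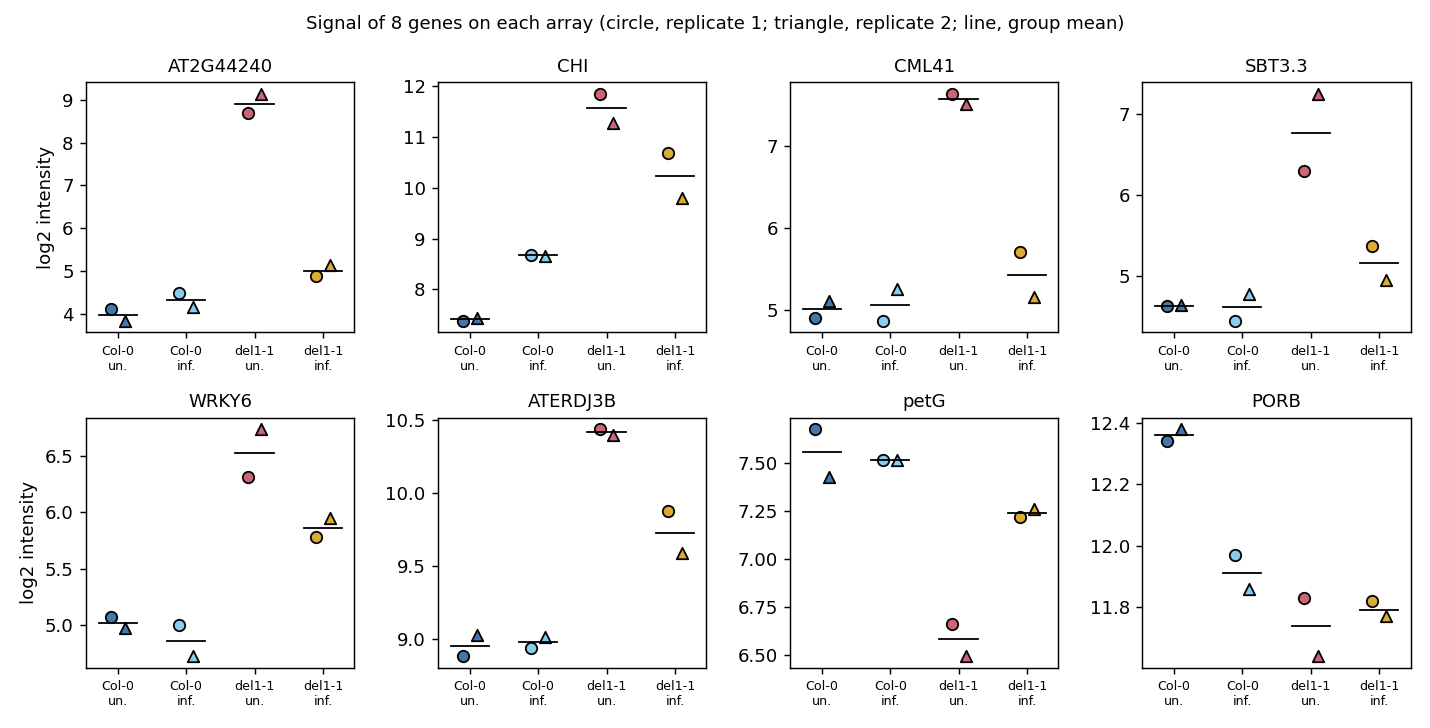
Log2 intensity of 8 genes on each array, in uninfected (un.) and infected (inf.) Col-0 and del1-1; circles are replicate 1, triangles replicate 2 and lines group means, and each panel has its own axis, which does not start at 0. For AT2G44240, CHI, CML41, SBT3.3, WRKY6 and ATERDJ3B both uninfected del1-1 arrays lie above all others, and for petG both lie below all others.

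The comparison of infected del1-1 with infected Col-0 asked whether the genotypes differ once the fungus is present. No probe set passed (smallest adjusted p = 0.169 in limma), 324 had an unadjusted p under 0.05 (813 with the replicate block), where 1137 would be expected by chance, and the unmoderated linear model also called 0. ATERDJ3B was 1.69-fold higher in del1-1, WRKY6 2.01-fold and WRKY53 2.88-fold. The defensin genes PDF1.2 and PDF1.2b had log2 differences of 2.88 ± 1.10 (SE) and 2.87 ± 0.95, the ER lectin gene OS9 0.41 ± 0.15, FBL17 0.50 ± 0.11, AT3G07590 0.58 ± 0.10 and AT4G31880 0.55 ± 0.11. Among lower values were AT5G11420 at -0.51 ± 0.10, AT3G55420 at -0.55 ± 0.12, ndhJ at -0.49 ± 0.11, atpI at -0.57 ± 0.18, rps2 at -0.81 ± 0.39 and TMT2 at -0.45 ± 0.18. None of these genes passed, and without 1 array rps2 ranged from -1.13 to -0.50 and TMT2 from -0.63 to -0.28. Differences of at least 2-fold in the same direction in both same-numbered pairs were found for 40 probe sets higher and 21 lower in del1-1, against 9 in opposite directions, a count chosen after the data were seen. Of the fixed lists' members 0 passed over all probe sets, and 4 passed, all higher, adjusted over the list alone, again in lists with 1 or 2 measured members.

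As lists, the endoplasmic reticulum stress genes (14 of 14 higher, median 0.26, adjusted p = 6.08e-05) and the named defence genes (15 of 20 higher, median 0.28, adjusted p = 0.0115) rose in infected del1-1 relative to infected Col-0. Both calls were lost with an estimated correlation (adjusted p = 0.477 and 0.677). Plastid-encoded photosynthesis genes (30 of 43 lower, median -0.07, adjusted p = 0.00172), plastid-encoded gene expression genes (18 of 20 lower, median -0.29, adjusted p = 6.08e-05) and nuclear photosynthesis genes (21 of 24 lower, median -0.16, adjusted p = 0.00172) fell, calls also lost with an estimated correlation (adjusted p = 0.677 for each). Markers of flower, pollen and seed also fell (11 of 13 lower, median -0.09, adjusted p = 0.0385), a call absent with the replicate block (adjusted p = 0.0975) and with an estimated correlation (adjusted p = 0.677). Without Col-0 infected replicate 1 the count of lists was 1. Replication and mitosis lists had medians of -0.02 (adjusted p = 0.78) and -0.06 (adjusted p = 0.839).

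Over both states together, del1-1 differed from Col-0 in 2 probe sets, both higher. The unnamed probe set with the 17.8-fold difference above was 9.53-fold higher (adjusted p = 0.00407) and AT2G44240 7.03-fold higher (adjusted p = 0.0449). The value of AT2G44240 averages 2 unlike states and comes mostly from the uninfected leaves. On infected leaves its log2 intensities were 4.87 and 5.15 in del1-1, against 4.49 and 4.16 in Col-0. On uninfected leaves they were 8.68 and 9.14, against 4.12 and 3.83. With the replicate block 2 were called, of which 1 was shared: AT2G44240 no longer passed (adjusted p = 0.0757) and AT1G68620 did (4.04-fold, adjusted p = 0.0179, against 0.82 without the block). An unadjusted p under 0.05 was found for 1316 probe sets without the block and 2478 with it. CHI was 7.29-fold higher, ATERDJ3B 2.16-fold, WRKY6 2.39-fold and AT4G16660 1.88-fold, and ndhJ, petG, AT5G11420 and AT3G61550 had log2 differences of -0.60 ± 0.08 (SE), -0.63 ± 0.09, -0.56 ± 0.07 and -0.90 ± 0.14, none past the threshold. Of the 24 added lists 7 passed, with 14 of 14 endoplasmic reticulum stress genes higher (median 0.36, adjusted p = 5.01e-09) and 42 of 43 plastid-encoded photosynthesis genes lower (median -0.18, adjusted p = 1.45e-14), and 0 passed with an estimated correlation (adjusted p = 0.145 for both lists with an estimated correlation). The 7 calmodulin-like genes passed without the replicate block and not with it (adjusted p = 0.0442 and 0.15), and mitochondrial respiration genes the reverse (adjusted p = 0.131 and 0.0347, and with the block and an estimated correlation adjusted p = 0.348). Genes of xyloglucan hydrolases, expansins and endoglucanases passed only with the block as well (median -0.06, adjusted p = 0.121 and 0.0347, and with the block and an estimated correlation adjusted p = 0.524). The fixed photosynthesis list fell too (7 of 7 lower, median -0.19, adjusted p = 0.0121, and adjusted p = 0.281 with an estimated correlation), a call lost without Col-0 uninfected replicate 1, Col-0 infected replicate 1, del1-1 uninfected replicate 2 or del1-1 infected replicate 2. Of the fixed lists' members 6 passed, all higher, adjusted over the list alone, in lists with 1 or 2 measured members. With the replicate block 8 passed, 1 of them lower, in the abscisic acid list with 3 measured members. The count of 2 probe sets became 1 without either uninfected Col-0 array and 0 without any of the other 6 arrays.

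Infection of Col-0 asked what the fungus does to wild-type leaves at 5 days. No gene was called higher or lower between infected and uninfected Col-0. Among the named genes AT1G09500 was 4.67-fold higher, CHI 2.39-fold higher and ATATH8 1.51-fold higher on infected leaves. IAA29 had a log2 difference of -2.52 ± 0.50 (SE), AT5G12940 -1.56 ± 0.23, AT4G32460 -1.12 ± 0.19, XERICO, a gene that raises abscisic acid, -1.04 ± 0.36, UGT73B1 -0.95 ± 0.25, PORB -0.45 ± 0.11 and the glucosinolate gene AOP1 0.98 ± 0.38. The defence regulators WRKY53 and GRX480 were at -0.66 ± 0.44 and -0.29 ± 0.46. Without 1 array WRKY53 ranged from -1.16 to -0.16, AOP1 from 0.51 to 1.45, XERICO from -1.46 to -0.63 and UGT73B1 from -1.28 to -0.61, and GRX480, from -0.91 to 0.33, changed direction. All of these adjusted p-values were 1 in limma, and 194 probe sets had an unadjusted p under 0.05 (440 with the replicate block) where chance gives 1137. The unmoderated linear model and the replicate block also called 0, and 0 members of the fixed lists passed adjusted over the list alone. No list passed: 8 of 20 named defence genes were higher (median -0.08, adjusted p = 0.814), 10 of 14 endoplasmic reticulum stress genes (median 0.06, adjusted p = 0.975) and 25 of 43 plastid-encoded photosynthesis genes (median 0.02, adjusted p = 0.975). This count of 0 lists became 2 without dim probe sets. It also rose in some fits without 1 Col-0 array. There the replicate numbers were unbalanced between infected and uninfected leaves, so part of the difference between the numbers entered.

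Infected and uninfected Col-0 differed in opposite ways in the 2 replicate numbers. Across probe sets the log2 changes of replicate 1 and replicate 2 correlated at -0.27, and 138 probe sets changed at least 2-fold in opposite directions against 8 higher and 14 lower in both. Genes are not independent replicates, so this correlation carries no p-value. Infected plants stood in a growth chamber of their own, so infection and chamber are joined in every array.

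Infection of del1-1 asked the same of the mutant. AT2G44240 was 14.9-fold lower on infected than on uninfected del1-1, at 5.01 ± 0.20 (SD, n = 2) against 8.91 ± 0.32, and did not pass (adjusted p = 0.101 in limma). It was the 1 call when 1 probe set per gene was tested. AT1G44130 was 2.16-fold lower and AT1G06620 3.04-fold lower. CML41 was at -2.14 ± 0.23 (SE) on the log2 scale. PYK10 had a log2 difference of -1.64 ± 0.25 (SE), SBT3.3 -1.61 ± 0.34, UGT76B1 -1.93 ± 0.52, GRX480 -1.24 ± 0.46, CRT1b -0.95 ± 0.39, ATERDJ3B -0.68 ± 0.13 and WRKY6 -0.66 ± 0.19. Without 1 array UGT76B1 ranged from -2.76 to -1.10 and CRT1b from -1.46 to -0.44. On the higher side were AT1G64680 at 1.05 ± 0.18, AT3G61080 at 1.00 ± 0.17, LHCB4.3 at 0.97 ± 0.27, NdhN at 0.75 ± 0.18, AT1G07440 at 0.74 ± 0.12, petG at 0.66 ± 0.13 and psbH at 0.55 ± 0.11. No probe set passed over all tested; 450 had an unadjusted p under 0.05 (848 with the replicate block), and the unmoderated linear model called 0. Of the fixed lists' members 2 passed, both lower, adjusted over the list alone, in lists with 2 measured members each. At least 2-fold changes in both replicate numbers were found for 70 probe sets lower and 8 higher, against 72 in opposite directions.

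The lists that separated uninfected del1-1 from Col-0 moved the other way on infection of del1-1. All 43 plastid-encoded photosynthesis genes were higher on infected leaves (median 0.26, adjusted p = 1.51e-17), as were 19 of 20 plastid-encoded gene expression genes (median 0.25, adjusted p = 1.71e-05), 22 of 24 nuclear photosynthesis genes (median 0.22, adjusted p = 3.89e-06) and 7 of 7 genes of the photosynthesis list fixed before the data were examined (median 0.14, adjusted p = 0.0165). These calls were lost with an estimated correlation (adjusted p = 0.166, 0.563, 0.478 and 0.297), and that of the fixed list also without del1-1 infected replicate 1. Endoplasmic reticulum stress genes fell (13 of 14 lower, median -0.21, adjusted p = 7.61e-05), as did the named defence genes (13 of 20 lower, median -0.41, adjusted p = 0.000118) and the beta-glucosidase and ER body genes (19 of 27 lower, median -0.22, adjusted p = 7.61e-05), calls lost with an estimated correlation as well (adjusted p = 0.166 for each). Calmodulin-like genes passed too (adjusted p = 0.00945) with a median of 0 and a mean of -0.24, which CML41 sets, and not with the replicate block (adjusted p = 0.11) or an estimated correlation (adjusted p = 0.261). Both comparisons use the uninfected del1-1 arrays, whose deviations enter them with opposite signs, so these list changes are not independent of those between the uninfected genotypes.

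**Figure D3:**
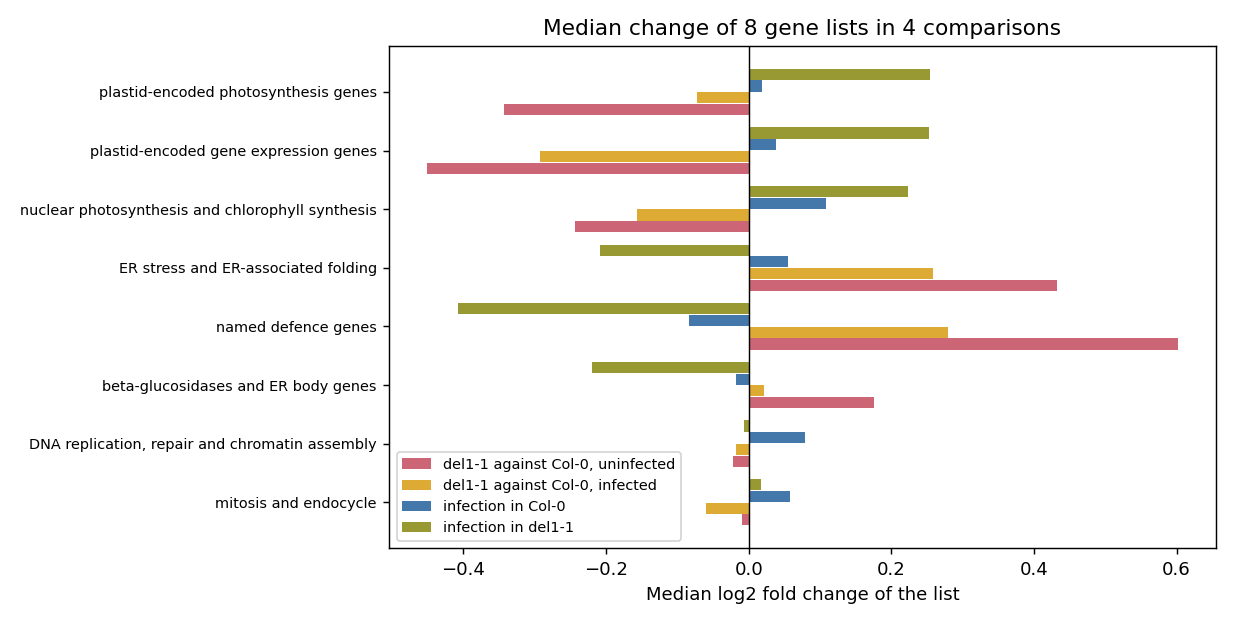
Bars give the median log2 fold change of 8 gene lists, 1 bar per comparison, with zero marked. Named defence genes have medians of 0.60 between the uninfected genotypes, 0.28 between the infected genotypes, -0.08 on infection of Col-0 and -0.41 on infection of del1-1, and the plastid-encoded photosynthesis genes have -0.34, -0.07, 0.02 and 0.26.

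The interaction asked whether the infection change differed between the genotypes. It equals the genotype difference on infected leaves minus that on uninfected leaves, so its values are not independent of those 2 comparisons. AT2G44240 had the smallest adjusted p, 0.423, with a difference of -4.24 ± 0.32 (SE) between its infection changes in del1-1 and Col-0. CML41 was at -2.20 ± 0.33, AT3G02840 at -1.51 ± 0.24, AT1G44130 at -1.19 ± 0.19, AT5G12940 at 1.51 ± 0.32, AT4G32460 at 1.17 ± 0.26 and AT3G61080 at 1.02 ± 0.24. No probe set passed in limma, 264 had an unadjusted p under 0.05 (560 with the replicate block), and the unmoderated linear model called 1. Of the 24 added lists 8 passed with the preset correlation (6 with the replicate block) and 0 with an estimated correlation (lowest adjusted p = 0.392). The count of 8 became 1 without Col-0 infected replicate 2, 3 without Col-0 uninfected or del1-1 infected replicate 1, 4 without Col-0 uninfected replicate 2 or del1-1 uninfected replicate 1, and 5 without del1-1 infected replicate 2. Of the fixed lists 0 passed without and 1 with the replicate block, the photosynthesis list (adjusted p = 0.0775 and 0.0322), which did not pass with the block and an estimated correlation (adjusted p = 0.179). Of their members 1 passed, lower, adjusted over the list alone, in a list with 2 measured members.

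The infection changes of the 2 genotypes, which share no array, correlated at 0.17 across 22746 probe sets. Within a replicate number the correlation was 0.34 in replicate 1 and 0.33 in replicate 2. Across numbers it was -0.27 for Col-0 replicate 1 with del1-1 replicate 2 and -0.12 for the reverse. Without Col-0 uninfected replicate 2 the overall value was -0.03, and without Col-0 infected replicate 1 it was 0.08. The change between uninfected genotypes and the infection change in Col-0 correlated at 0.32, with a covariance of 0.0338. Both use the uninfected Col-0 arrays, and simulated unchanged groups sharing those arrays gave a correlation of 0.50 and a covariance of 0.0734 with the unblocked spread, or 0.0311 with the spread of the blocked fit. The unblocked spread holds variation shared by same-numbered arrays, which cancels in the real differences but was drawn separately for each simulated group. The value of 0.0734 is therefore too high a reference, and nothing is drawn from the difference of -0.0396 to it. With the blocked spread the observed covariance differed from the simulated one by 0.00276. That simulation too holds no spread shared by the arrays of 1 chamber. With only 2 control arrays, the control group could not be divided with 2 arrays on each side. Taking each change from a different replicate number, so that no array was shared, gave correlations of -0.11 and -0.0038. The overall value was 0.63 and 0.67 without Col-0 uninfected replicate 1 and 2, and 0.03 without Col-0 infected replicate 2. With 1 uninfected Col-0 array left, both changes subtract that same array, which by itself raises the correlation. The values of 0.63 and 0.67 are therefore no sign of a closer resemblance.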

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

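The test of brightness below was set before its result was seen. That of RNA degradation was too, but its control gene actin was added only after a first run on GAPDH and ubiquitin had been seen. The tests of plastid RNA carry-over, growth chambers and exchanged labels were chosen after the patterns were seen. For 8 added lists the infection change differed between the genotypes in camera's test of the interaction. The difference, del1-1 minus Col-0, had a median log2 value of 0.262 for plastid-encoded photosynthesis genes (adjusted p = 1.91e-11), 0.187 for plastid-encoded gene expression genes (0.00493) and 0.149 for nuclear photosynthesis genes (0.00636). It was -0.230 for endoplasmic reticulum stress genes (0.00636), -0.319 for named defence genes (0.0143), -0.155 for beta-glucosidase and ER body genes (0.012), -0.404 for calmodulin-like genes (0.0333) and -0.088 for markers of flower, pollen and seed (0.0333). The count of 8 fell to 1 without Col-0 infected replicate 2. None passed with an estimated correlation or with fry, and with the replicate block the calmodulin-like genes (0.123) and the flower, pollen and seed markers (0.118) did not pass. The interaction uses the uninfected arrays of both genotypes with the opposite sign to the comparison of uninfected genotypes. These list values are therefore not independent of that comparison, and are no separate evidence on the response to infection.

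A first pattern is that photosynthesis transcripts were lower and endoplasmic reticulum transcripts higher in uninfected del1-1. A brightness-dependent shift from normalization is argued against: 0% of 10000 random lists matched on mean signal had a median as low as the -0.343 of the plastid-encoded photosynthesis list, and the central range used in the test ran from -0.08 to 0.02. RNA degradation stays open. The 3′ minus 5′ log2 signal of 3 control genes differed between uninfected del1-1 and Col-0 by -0.20 in replicate 1 and 0.17 in replicate 2. The mean, -0.01, lay under the SD of 0.11 over the 8 arrays, as without degradation, although each difference exceeded it. A second set of control probe sets for the same genes was left out of the test. There the 3′ to 5′ gap was wider in uninfected del1-1 in both numbers, though only slightly in replicate 1. For ubiquitin in replicate 2 the signals were 13.42 and 12.72, against 13.2 and 12.84 in Col-0. The outcome thus depends on the set used. Carry-over of plastid RNA into the labelling would not by itself lower nuclear transcripts, and all 24 nuclear photosynthesis genes were lower too. This test was chosen after the pattern was seen, and the nuclear list did not pass in camera with an estimated correlation (adjusted p = 0.275). It cannot tell whether carry-over lowered the plastid-encoded transcripts, so carry-over stays open for them. The cause stays open, and chance is among the possibilities, since the calls were lost with an estimated correlation (adjusted p = 0.089 for both lists).

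A second pattern is that infection changes largely did not recur between replicate numbers, more so in Col-0 than in del1-1, where 70 probe sets were at least 2-fold lower in both numbers and 72 went in opposite directions. Conditions that differ between the chambers of each replicate number could produce it: the mean correlation of Col-0 and del1-1 infection changes was -0.197 across numbers, against 0.34 and 0.33 within. An exchange of infected and uninfected in 1 replicate number would make the changes mirror each other in both genotypes. The correlation between numbers was -0.27 in Col-0 and -0.0177 in del1-1, which settles it neither way.

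The third pattern is that most named defence transcripts were higher in the arrays labelled uninfected del1-1 than in those labelled infected, with 7 of 20 higher on infected del1-1 and the defensin gene PDF1.2 2.03-fold higher there as exceptions. A constitutive defence state of the mutant is a candidate explanation that was not tested. Another is an exchange of labels, of Col-0 infected with del1-1 uninfected or of the 2 del1-1 groups. If arrays that shared a chamber deviate together, the pairs sharing one by their labels should correlate best: their mean was 0.653, against 0.522 for the pairs that the first exchange would place together and 0.459 for the second, but it rests on the infected pair (0.787), as the uninfected pair (0.519) lay below the del1-1 pair (0.534). The means passed the first bound written, 1 SD of the 6 correlations (0.128), the first exchange by a thin margin; a bound of 2 SDs, put in its place after that outcome was seen and then withdrawn, would have left both open. The exchanges are therefore not ruled out, and DEL1, which would check the genotype, was not analysed by name here.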

How the results depend on the processing

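Fits of only the groups compared with the replicate block, all settings of the added lists, the count of 2-fold differences in both numbers and the changes taken from different replicate numbers were chosen after seeing the data. Of 1915 values of named genes under alternatives, 1889 kept their direction and side of the threshold, 24 no longer passed, 1 newly passed and 1 reversed. The last was GRX480 on infection of Col-0, which ranged from -0.91 (without Col-0 uninfected replicate 1) to 0.33 without 1 array, and was 0.33 without Col-0 uninfected replicate 2. In these fits the replicate numbers were unbalanced between the infected and uninfected Col-0 arrays. The 24 lost calls were all of AT2G44240, between the uninfected genotypes or over both states, the only named gene values called in the main fit. The other values had no call to lose, so their staying short of the threshold is no measure of stability.

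For uninfected del1-1 against Col-0 the count of 3 became 0 with only the arrays of these groups, with or without the replicate block, 1 with 1 probe set per gene and 1 at an adjusted p under 0.01. For the mean of both states the count of 2 became 0 in the unmoderated linear model and 1 with 1 probe set per gene, with array weights and at an adjusted p under 0.01. One probe set per gene removes the unnamed probe sets by construction. It gave 1 call for infection in del1-1, and the unmoderated model 1 for the interaction. Leaving out 1 array gave 0 to 0 for the uninfected genotypes and 0 to 1 for the mean of both states. The lone array of a group is then assumed to vary like the others. Its comparisons also take up part of the difference between the replicate numbers, since these fits had no block. Array weights can differ only between groups here.

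Lists fixed first that passed numbered 1 in infection of del1-1, between uninfected genotypes and over both states, and 0 in each with an estimated correlation and with fry; the interaction gave 1 with the replicate block. Added lists went from 7, 7, 6, 7 and 8 (infection in del1-1, uninfected, infected, both states, interaction) to 0 in each with an estimated correlation and with fry. For infection in Col-0, 2 passed without dim probe sets. Without 1 array the fixed lists gave 0 to 1 in 5 comparisons and 0 to 0 for infection in Col-0. The added lists gave 0 to 6 for infection in Col-0 (6 without Col-0 uninfected replicate 1, 4 without Col-0 infected replicate 2), 5 to 7 for infection in del1-1, 6 to 9 between uninfected and 1 to 6 between infected genotypes, 6 to 8 over both states and 1 to 7 for the interaction (1 without Col-0 infected replicate 2, 3 without Col-0 uninfected or del1-1 infected replicate 1).

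The agreement of the infection changes, 0.17, ranged from -0.029 to 0.21 without 1 array and was -0.197 with changes from different replicate numbers. The resemblance of the genotype and infection changes, 0.32, ranged from 0.031 to 0.67 and was -0.056. Its highest values came without an uninfected Col-0 array, where both changes subtract the same single array. Apart from the numbers of genes and arrays left, the cause was not tested. Signal over background was not analysed here, so dim probe sets are not told from absent transcripts.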

Other observations

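The contrast of replicate numbers was examined only after their separation had been seen, and it holds 4 same-group pairs of arrays. With group means in the model, limma called 933 probe sets, 536 higher and 397 lower in replicate 2, and 148 were at least 2-fold higher and 157 at least 2-fold lower in all 4 groups. Among genes with a symbol, the 10 with the smallest p on either side were looked at. COR27, a cold- and clock-regulated gene, was 62.7-fold higher in replicate 2 (adjusted p = 0.01), and the cold-regulated gene COR15B 4.54-fold higher (adjusted p = 0.0189). The thiamine synthesis gene THIC was 2.08-fold higher. On the other side, the jasmonate-related genes JRG21 and JMT, for a jasmonate methyltransferase, were 26.3-fold and 3.75-fold lower in replicate 2 (adjusted p = 0.0225 and 0.0233), the sugar transporter gene SWEET2 5.37-fold lower and the lectin gene JAL23 6.36-fold lower. COR27 in replicate 1 (3.33 to 4.17) and JRG21 in replicate 2 (3.82 to 4.02) were dim. The lowest array median was 5.24 on the log2 scale, so the size of these 2 folds is uncertain.

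As lists, all 10 autophagy genes were higher in replicate 2 (median 0.33, adjusted p = 0.0276), and jasmonate and wound genes were lower (8 of 12, median -0.27, adjusted p = 0.0276). Nuclear photosynthesis genes (22 of 24 lower, median -0.18, adjusted p = 0.000288), plastid-encoded gene expression genes (19 of 20 lower, median -0.23, adjusted p = 0.00168) and the fixed photosynthesis list (7 of 7 lower, median -0.19, adjusted p = 0.00217) were lower. With an estimated correlation none passed (adjusted p = 0.0872 for the fixed list, 0.561 or 0.706 for the others). No explanation of the difference between the numbers was tested.

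The difference between the genotypes over both states was set against other splits of the arrays, chosen before their results were seen. The look at splits balanced for replicate number was added after. Splits with 2 arrays per part within each infection state number 18, too few for a share under 0.05. The real split gave 2 probe sets and 3 of the splits, itself included, gave at least as many. The highest of the others, 1550, divided the arrays by replicate number, which points to that structure of the samples. Among the 8 splits with 1 array of each number in every part, the real one gave 2 and the highest of the others 0. These 8 are also too few for a share under 0.05. Most of the others mix the genotypes within a part, where a genotype difference would itself widen the spread and lower the count.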
